A study of Mus musculus with 4 samples.

How the data were processed

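Genomic DNA of 4 liver tumours from 4 mice that had lost Trp53 in the liver was measured by array comparative genomic hybridization. In this assay tumour DNA and reference DNA carry different dyes and compete for the same oligonucleotide probes, so the ratio of the dyes gives the relative copy number of each probed position. Per the labels, tumour DNA carried Cy5 (red) and the reference carried Cy3 (green) on all 4 arrays, so no dye was swapped. The labels describe the reference as spleen DNA, pooled from 3 sex-matched littermates per the series design, whereas the labelling protocol names liver as the reference. Spleen is written for the reference here. The labels give the genotype Trp53-/- and male sex for both channels of every array. The tumours form 1 group and are numbered 1 to 4, with no meaning in the order.

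Per the file headers, the deposited files are the output of Agilent Feature Extraction, version 12.0.1.1, with probe positions on the mouse build mm9. The submitters' processing notes give version 12.0.0. Per the file headers, the deposited processed intensity of each channel was background-subtracted, detrended and dye-normalized within the array by 1 linear factor per channel. The deposited mean and background intensities were not normalized. The deposited log10 ratio of each spot was used only to check the direction, and it lay within 0.001 of the log10 ratio of the processed signals at 99.7% or more of the spots on each array. Each array held 174317 spots that were not controls. Positions on chromosomes 1 to 19, X and Y were given for 169093 probes, of which 159076 were autosomal, with a median spacing of 10184 bp. A gene name stood beside 107776 of these probes, for 22180 different names.

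From the deposited intensities, log2 of processed red over processed green was computed per spot. Spots flagged as non-uniform or as population outliers in either channel were left out (81, 258, 96 and 173 placed spots on the arrays of tumours 1 to 4). The 1000 probes spotted 5 times were averaged, and each array was centred on the median of its autosomal probes. No loess or quantile normalization was applied, since copy-number changes may shift many probes 1 way.

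Signal over background was high. In the reference channel 98.9% to 99.9% of the spots were well above background, and in the tumour channel 99.0% to 99.9%. The spread between neighbouring probes differed more. Its SD was 0.12, 0.36, 0.15 and 0.15 (log2) for tumours 1 to 4, and the file header of tumour 2's array put its derivative log ratio spread, 0.36, outside the accepted range. The number of arrays limits the precision of every mean over tumours.

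Each array was divided into segments by penalised least squares with an exact search for change points. The penalty was 3 times the logarithm of the number of autosomal probes times the noise variance. A segment was called gained or lost when it held at least 5 probes and its mean lay at or beyond 0.2 or -0.2. Uncalled gaps of fewer than 5 probes between calls of 1 direction were joined, and segments under 3 Mb were counted as focal. The odd and the even probes were segmented apart as a technical check of each array. Chromosome means, Trp53 and the antigen receptor loci were tested against 0 with exact two-sided sign-flip permutation tests over the 4 tumours. The smallest p that 4 tumours allow is 0.125, so no such test can pass 0.05. Gene means, over genes with at least 2 probes on 1 chromosome, were tested against 0 with limma 3.58.1 (lmFit with an intercept and eBayes, in R 4.3.3) and Benjamini-Hochberg adjustment. This test leaves out the spread of the reference. A gene took the call at its middle probe. Counts of genes called in at least 2 tumours, calls in gene lists and genes called alike in pairs of tumours were set against 10000 circular shifts of each tumour's calls along the autosomes, which keep segment lengths. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0 was used for these steps.

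The tests, the 9 gene lists and the rule for named genes were fixed before the data were examined. The rule took Trp53, and up to 4 members of each list with the largest segment means among called members, or the 2 largest means where no member was called. For the lists this rule was applied to autosomal members, and members on X are given apart. It took up to 3 of the largest called segments per tumour, given here for the autosomes and apart for X and Y. It also took regions called alike in at least 3 tumours and the 5 shortest called alike in at least 2. Of the list members that the rule took, 1 is not reported here. Of the 210 list entries, 196 were matched to a name on the array, in part through synonyms in a RefSeq gene table of assembly GRCm38, from which no coordinate was used. No gene name on the array marked an antigen receptor locus, so the planned selection by name gave no probe. Windows between the nearest array genes flanking each locus were used in its place, and this choice was made after seeing the data.

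The segmentation, shift and limma steps were tested on simulated data. Planted segments of 10 probes at 0.6 were recovered in 100% of cases at the noise of tumours 1, 3 and 4 and in 0% at the noise of tumour 2. Segments of 500 probes at 0.3 were recovered in 100% of cases on all 4 arrays. Those of 10 probes at 0.3 were recovered in 21.9%, 0%, 5.3% and 1.6% of cases for tumours 1 to 4. Segments of 50 probes at 0.3 were recovered in 1.07% of cases for tumour 2 and in 100% for the others. Over 13919 simulated genes, limma recovered 45 of 100 genes changed by 0.3 and 98 of 100 changed by 0.6, with 0 false calls. The simulated noise was drawn independently for each array. Probe values of tumours 2, 3 and 4 with segment means subtracted correlated at 0.35 to 0.50, so false calls from noise shared between arrays were not tested. In 100 simulations without recurrence, 5 gave a shift p under 0.05 for genes gained in at least 2 tumours, and 8 for the tumour suppressor list. These simulated profiles were themselves random shifts of the called profiles, so they check the calculation and not whether shifts are a fair comparison. Alternatives covered background correction, centring, an intensity trend, flagged and dim probes, the penalty, the call threshold, segment size, a running median, the gene summary, the slide as a random block and leaving out each tumour. Added after seeing the data were a probe GC trend, turned signs of tumours 1 and 4, autosomal genes alone, leaving out tumours 1 and 4, and 1 Mb windows or autosome means as units. Nothing in the labels tied tumours to litters. The sign-flip and limma p-values measure the spread between these 4 tumours, and the shift p-values measure where calls fall along the autosomes.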

Results

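Copy number was measured across the genome in 4 liver tumours (tumours 1 to 4) from mice that had lost Trp53, the gene of the p53 tumour suppressor, in the liver. Each tumour was hybridized with pooled spleen DNA on its own array, so each value below is a log2 ratio of tumour over reference. The 4 arrays lay on 2 slides, with tumours 1 and 2 on 1 slide and tumours 3 and 4 on the other. The design has no second group, and the question it puts is which chromosomes, regions and genes were gained or lost in these tumours.

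The targeted gene was examined first. Trp53 was covered by 2 probes on chromosome 11 (mm9), at 69397121 to 69397180 and at 69404685 to 69404744, and these went opposite ways. The first read -0.53, -0.78, -0.07 and -0.76 in tumours 1 to 4, with a mean of -0.54 ± 0.33 (SD, n = 4), below 0 in 4 of 4 tumours (exact sign-flip p = 0.125, the smallest possible). The second read 0.14, 0.51, 0.31 and 0.17, with a mean of 0.28 ± 0.17 (SD, n = 4; exact sign-flip p = 0.125). Their average was -0.13 ± 0.18 (SD, n = 4), which was not distinguishable from 0 (exact sign-flip p = 0.25; limma adjusted p = 0.424). The 231 flanking probes within 1 Mb averaged 0.027 ± 0.059 (SD, n = 4), and no segment at Trp53 was called in any tumour. The labels do not say which part of the gene was deleted and give the same genotype for both channels, so these probes may lie outside the deleted part and do not check the genotype.

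Chromosome 15 had the highest mean of the autosomes in every tumour. Its mean log2 ratio was 0.21, 0.29, 0.14 and 0.24 in tumours 1 to 4, with an average of 0.22 ± 0.063 (SD, n = 4), a ratio of 1.16 and above 0 in 4 of 4 tumours. Chromosomes 9 and 12 had the lowest averages. Chromosome 9 read -0.18, -0.003, -0.12 and -0.20, an average of -0.12 ± 0.086 (SD, n = 4), and chromosome 12 read -0.17, -0.034, -0.11 and -0.18, an average of -0.12 ± 0.067 (SD, n = 4). Both were below 0 in 4 of 4 tumours, with the values of tumour 2 nearest to 0. The averages of the other 16 autosomes lay between -0.034 and 0.019.

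The exact sign-flip test gave p = 0.125 for each of chromosomes 15, 9 and 12, the smallest that 4 tumours allow (adjusted p = 0.375). A limma fit over the 19 autosome means, chosen after seeing the data, gave an adjusted p of 0.00629 for chromosome 15, 0.0953 for chromosome 9 and 0.0528 for chromosome 12. Turning the sign of tumour 4 lowered the chromosome 15 average to 0.10 and turning that of tumour 1 lowered it to 0.11.

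**Figure D1:**
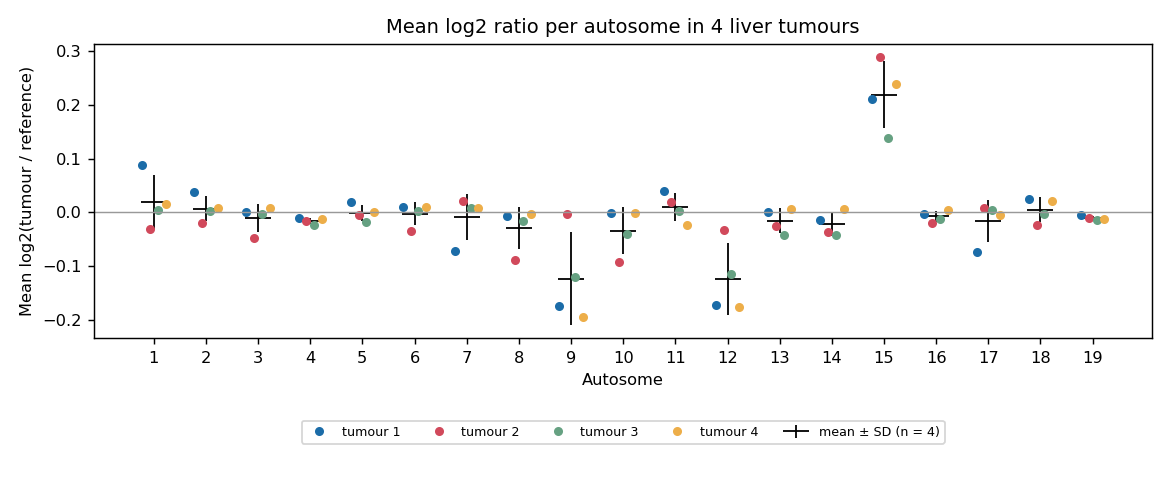
Mean log2 ratio of tumour over reference (vertical axis) of each autosome (horizontal axis), with a point per tumour and a bar for the mean ± SD over 4 tumours. Chromosome 15 lies above 0 in all 4 tumours, with an average of 0.22, and chromosomes 9 and 12 average -0.12 each.

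The called changes covered a small part of the autosomes. They covered 4.56%, 4.57%, 0.175% and 7.64% of the covered autosomal length in tumours 1 to 4, an average of 4.24 ± 3.07% (SD, n = 4). The odd and the even probes of each array, segmented apart, gave 4.41% and 4.45% for tumour 1, 4.48% and 4.32% for tumour 2, 0.0895% and 0.0157% for tumour 3, and 7.37% and 5.32% for tumour 4. All of chromosome 15 was called gained in tumours 1 and 2. In tumour 4 the called gain on chromosome 15 held 2 stretches of 72.7 Mb and 10.7 Mb, and in tumour 3 the mean of 0.14 lay below the call threshold of 0.2. At the chosen setting broad losses were called in tumour 4 alone on chromosome 9 (32.4 Mb and 20.1 Mb) and chromosome 12 (33.7 Mb and 4.71 Mb), where the chromosome means of tumours 1 and 3 lay between -0.11 and -0.18, short of the threshold. The whole-chromosome means of tumour 4, -0.20 and -0.18, lay close to it too. An uncalled stretch of its chromosome 9 had a segment mean of -0.197, and one of its chromosome 15 a mean of 0.186. The ends of its called stretches there need not be ends of copy-number changes. In tumour 2 a loss of 4.11 Mb on chromosome 2 averaged -0.23.

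Tumours 1 to 4 held 16, 5, 8 and 20 called autosomal segments, 49 in all, of which 39 were focal and 10 broad. The focal calls include losses of 2.32 Mb on chromosome 9 and 2.15 Mb on chromosome 12 in tumour 4, beside its broad losses there. The array of tumour 2, with a neighbour SD of 0.36 against at most 0.15 on the others, gave 2 focal calls against 15, 8 and 14. The shares and counts depend on the setting: the average share was 13.9% at a threshold of 0.1 and 0.536% at 0.3. Under normexp background correction the shares were 14.09%, 5.79%, 0.0999% and 14.01% in tumours 1 to 4, so that of tumour 1 was as high as that of tumour 4. With the running median the share of tumour 2 was 9.77%.

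**Figure D2:**
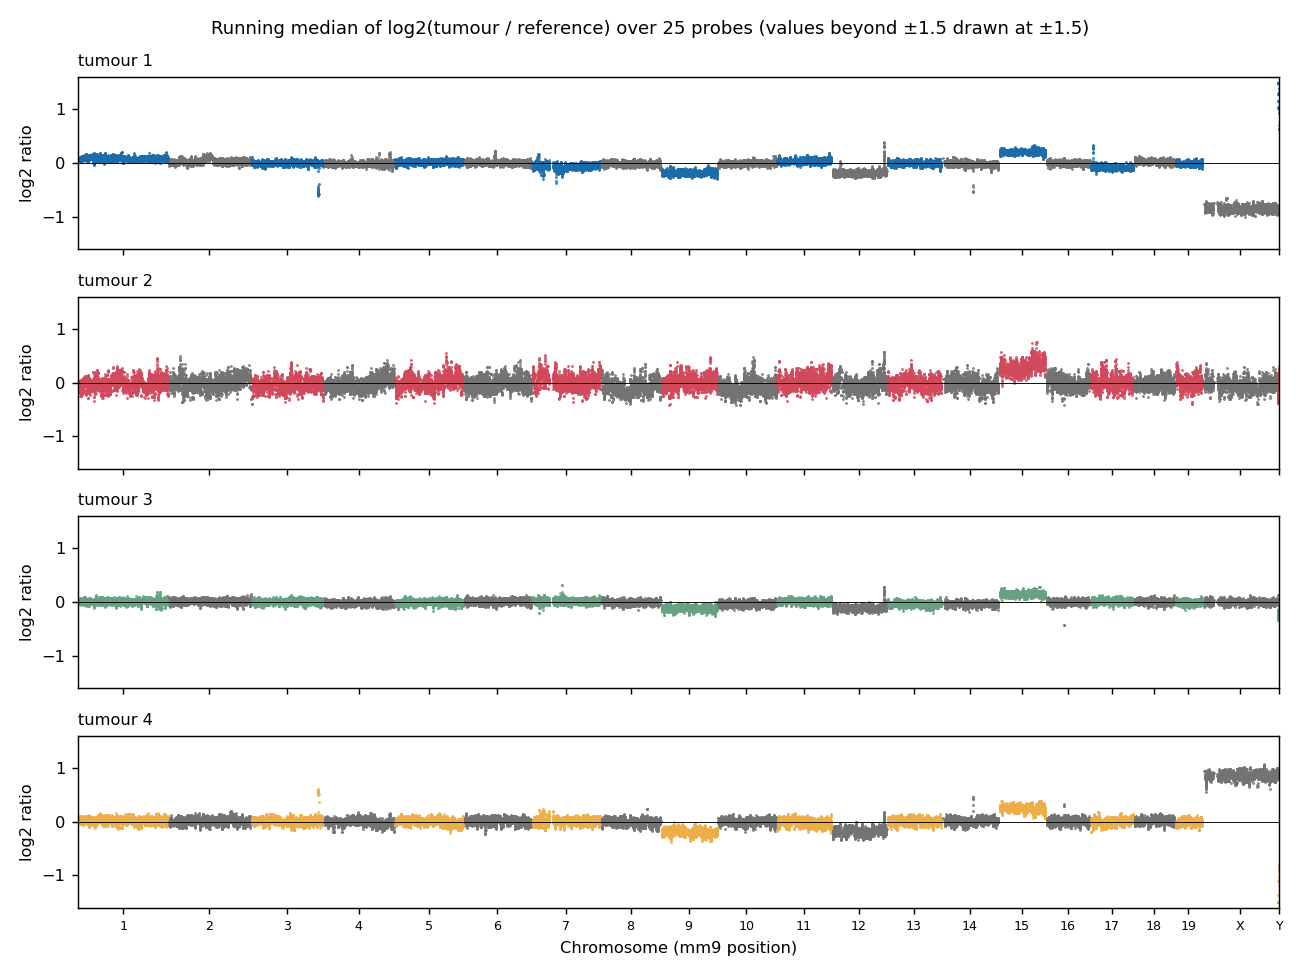
Running median over 25 probes of the log2 ratio of tumour over reference (vertical axes, drawn at the limit where beyond 1.5) along the mouse chromosomes (horizontal axis, mm9), with a panel per tumour. Chromosome 15 lies above the line in each panel, and chromosome X lies at -0.82 in tumour 1 and at 0.84 in tumour 4.

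No single gene passed the test of its mean over the tumours. Of 13919 genes with at least 2 probes, 0 were higher and 0 lower past an adjusted p of 0.05 in limma, and 2219 had an unadjusted p under 0.05. With segment means in place of probe means 533 genes passed as higher, all on chromosome 15, and 185 as lower, all on chromosome 12. Genes that lie in the same segments share their values in this setting, so these counts repeat a few stretches and are not independent results. With the slide as a random block 169 genes passed as higher, 163 of them on chromosome 15, and 192 as lower, 99 on chromosome 9 and 77 on chromosome 12. That fit used a correlation of -0.31 within slides, and a negative correlation narrows the standard error of a mean.

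Recurrent gains were nearly all on chromosome 15. Of 21341 autosomal genes, 845 were gained in at least 2 tumours, 844 of them on chromosome 15, and 448 in at least 3. Circular shifts of the profiles averaged 102 genes, with a highest value of 1337 (one-sided permutation p = 0.0116). By the call at its middle probe, no gene was lost in at least 2 tumours at the chosen setting (permutation p = 1). Short losses called in 2 tumours at Crxos1 and within Lsamp, given below with the focal segments, did not enter this count. Without tumour 1, and likewise without tumour 2, the count of gained genes was 448 (permutation p = 0.0315), and with tumours 2 and 3 alone it was 1 (permutation p = 0.158). At a threshold of 0.1, 845 genes were gained in at least 2 tumours (permutation p = 0.0819) and 2052 were lost (permutation p = 0.0439). At a threshold of 0.3 the count of gained genes was 0 (permutation p = 1). Genes lost in at least 2 tumours numbered 2019 under normexp background correction (permutation p = 0.0054) and 315 with a running median in place of segments (permutation p = 0.0005), so this count depends on the setting.

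The autosomal list members that were gained lay on chromosome 15 apart from 3, and they are given with their values. Among the liver cancer oncogenes, Myc, which encodes a growth-promoting transcription factor (61818043 to 61818102, 1 probe), was called gained in 3 tumours, with a gene value of 0.47 ± 0.42 (SD, n = 4). Under normexp background correction that single probe averaged -0.08. In the cell cycle list, Skp2, the F-box subunit of a ubiquitin ligase that targets p27, was called gained in 3 tumours and averaged 0.29 ± 0.17 (SD, n = 4). Espl1, which encodes separase, was called gained in 2 tumours and averaged 0.31 ± 0.27 (SD, n = 4). Stk3, a kinase of the Hippo pathway, was called gained in 3 tumours and averaged 0.18 ± 0.050 over 30 probes (SD, n = 4). Among the tumour suppressors, Arid2, a subunit of a chromatin remodeller, averaged 0.20 ± 0.079 (SD, n = 4), and Kmt2d, a histone methyltransferase listed on the array as BC032281, averaged 0.32 ± 0.32 (SD, n = 4). Both were called gained in 2 tumours, as was Xrcc6, the Ku70 gene of DNA end joining, at 0.15 ± 0.12 (SD, n = 4). The 3 gains elsewhere were called in tumour 2 alone, whose array was the noisiest. They were Akt1, a growth-signalling kinase on chromosome 12, and Stk11 and Map2k2 on chromosome 10, which encode the kinases LKB1 and MEK2. These 3 calls ended with the intensity trend or the probe GC trend removed and at a threshold of 0.3. Those of Stk11 and Map2k2 also ended with centring on the mode, with penalty factors of 1.5 and 6 and with the running median, and that of Akt1 with normexp background correction.

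At the chosen setting the autosomal list members that were lost lay on chromosomes 9 and 12 and were called in tumour 4 alone, 13 of 172 different autosomal list genes. These calls depend on the setting. List genes in uncalled stretches of chromosome 9 could lie close to the threshold in tumour 4, with a segment mean of -0.197 in such a stretch. With the intensity trend removed, 5 list genes were called lost in tumour 4, among them Keap1 and Cdc25a but none of the other losses named here, and its altered share was 4.41% against 7.64%. Under normexp background correction 24 were called lost in tumour 1 and 24 in tumour 4. At a threshold of 0.3 none was called lost in tumour 4. Of the losses of tumour 4 named here, those of Keap1, Foxa1, Sav1, Fos and Akt1 ended with a penalty factor of 6. That of Cdc25a ended with a factor of 1.5. With the running median those of Cdc25a, Foxa1, Fos and Akt1 ended. Atm, the DNA damage kinase, averaged -0.19 ± 0.052 over 10 probes (SD, n = 4), and Ctnnb1, the gene of beta-catenin, averaged -0.28 ± 0.13 (SD, n = 4). Map2k1, the gene of MEK1, averaged -0.16 ± 0.12 (SD, n = 4). Keap1, Cdc25a, Sav1, Fos, Apoa1 and Foxa1 lay within called losses of tumour 4, and their gene values averaged over the 4 tumours lay between -0.028 and 0.10. In tumour 4 itself Keap1 read -0.20, Cdc25a -0.16, Fos -0.20 and Apoa1 -0.28, and Sav1 (-0.016) and Foxa1 (-0.037) lay near 0. Akt1, gained in tumour 2, lay in a called loss of tumour 4. No autosomal large fragile-site gene was called, and the largest autosomal averages of that list were -0.12 for Immp2l and -0.052 for Large. Measured list members on chromosome X were 1 each in the tumour suppressor, hepatocyte and large fragile-site lists, namely Rps6ka3, Gpc3 and Dmd. They lay in the called loss of chromosome X in tumour 1 (gene values -0.75, -0.85 and -0.82) and in its called gain in tumour 4 (0.76, 0.87 and 0.88). On array 1 the reference channel had the unlike X level, -0.071 against -0.89 in the tumour channel. The call in tumour 1 therefore does not show a loss in the tumour.

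None of the 9 lists passed against the circular shifts over the autosomes, by net or by total calls. Gained minus lost calls were -1 for the p53 pathway, 1 for the liver cancer oncogenes, 1 for the tumour suppressors, 4 for the cell cycle and chromosome segregation list and 0 for receptor tyrosine kinase and RAS signalling. They were 2 for the Hippo pathway, 0 for DNA repair, -2 for the hepatocyte genes and 0 for the large fragile-site genes. For these net calls the smallest permutation p was 0.0974, for the hepatocyte genes, and every adjusted p was 0.795. For the total of gained and lost calls it was 0.0525, for the tumour suppressors, with 9 calls against a shift mean of 4.57, and the adjusted p values lay between 0.472 and 0.777. In limma 0 members passed over all genes. Adjusted over the list alone, 1 member passed in the p53 pathway, 2 in the oncogenes, 1 in the cell cycle list, 1 in DNA repair and 0 in the other 5 lists. The p53 pathway and DNA repair lists share Atm and had the same smallest limma p adjusted over the list, 0.0463. Their passing member may therefore be the same gene. With the sign of tumour 4 turned, the tumour suppressor list passed (net 9, adjusted permutation p = 0.0171). All lost calls of that list lay in tumour 4, so turning its sign makes the net equal the total of 9 calls.

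The called focal segments with the largest autosomal means often had opposite signs in different tumours. The reference was pooled from littermates and was not DNA of the tumour's own mouse. At these segments a change in the tumour therefore cannot be told apart from a difference between mice. In tumour 1 the 3 largest called segments were losses, at Crxos1 on chromosome 7 (16486467 to 16489975, -0.66), at Loxl2, Entpd4 and Slc25a37 on chromosome 14 (69877295 to 70070594, -0.60) and at Naip1 on chromosome 13 (101149716 to 101183591, -0.53). These stretches read 0.62, 0.49 and 0.33 in tumour 4. In tumour 3 the 3 largest were a gain at Cd244 and Itln1 on chromosome 1 (173444942 to 173508510, 1.25), a loss over 5 probes without a gene name on chromosome 7 (21316760 to 23368507, -1.07) and a loss within Lsamp on chromosome 16 (41701644 to 41794655, -0.96). Cd244 and Itln1 read 1.22 in tumour 2, in which no segment was called there. In tumour 4 the same chromosome 7 stretch read 1.89, Lsamp read 1.08, and Cyp2b13 and Cyp2b9, members of a drug-metabolising cytochrome P450 family on chromosome 7 (26789486 to 26973242), read 0.84. In tumour 1 the last stretch read -2.44 over 11 probes and the chromosome 7 stretch without a gene name -1.80 over 5, lower than any called autosomal segment of that tumour. Neither was called there, since the segmentation broke them into pieces of at most 2 and 3 probes. In tumour 2 the 3 largest were a loss within Lsamp (41701644 to 41773463, -0.96), chromosome 15 and a gain on chromosome 12 (113291384 to 116794594, 0.27). This gain overlapped the immunoglobulin heavy chain locus described below. Autosomal regions called alike in at least 2 tumours numbered 4, namely losses at Crxos1 (tumours 1 and 3) and Lsamp (tumours 2 and 3), and gains of chromosome 15 (tumours 1, 2 and 4) and of a stretch of chromosome 12 (114670169 to 115880517) in tumours 1, 2 and 3.

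**Figure D3:**
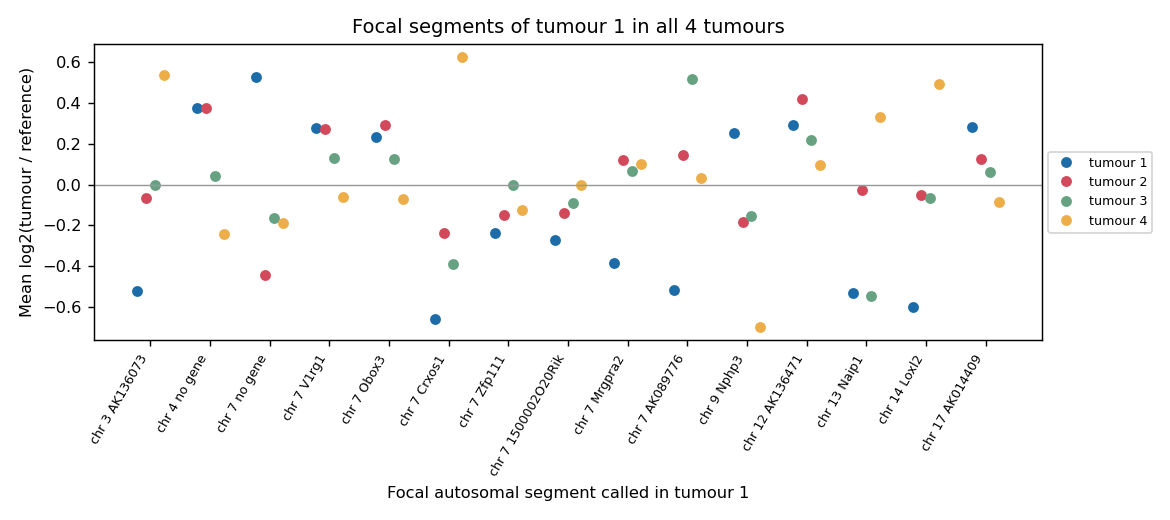
Mean log2 ratio of tumour over reference (vertical axis) in each of the 4 tumours at the 15 focal autosomal segments called in tumour 1 (horizontal axis, named by chromosome and first gene), with a point per tumour. The losses of tumour 1 at Crxos1 and Loxl2 read 0.62 and 0.49 in tumour 4.

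That stretch of chromosome 12 lay in the immunoglobulin heavy chain locus, Igh, which B cells rearrange with loss of DNA. Between the flanking genes Tmem121 and Zfp386 (114431475 to 117283759, 205 probes) the ratio exceeded that of the rest of chromosome 12 by 0.27, 0.29, 0.24 and 0.17 in tumours 1 to 4. The average excess was 0.24 ± 0.052 (SD, n = 4), above 0 in 4 of 4 tumours (exact sign-flip p = 0.125, the smallest possible; adjusted p = 0.75 over 6 loci). Without subtraction, the locus read 0.087, 0.25, 0.12 and -0.0089, an average of 0.11 ± 0.11 (SD, n = 4; exact sign-flip p = 0.25). The other 5 loci, relative to the rest of their chromosomes, averaged 0.042 for Igk, -0.028 for Igl, 0.013 for Tra and Trd, -0.0049 for Trb and 0.0067 for Trg, with exact sign-flip p values of 0.25 or more.

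**Figure D4:**
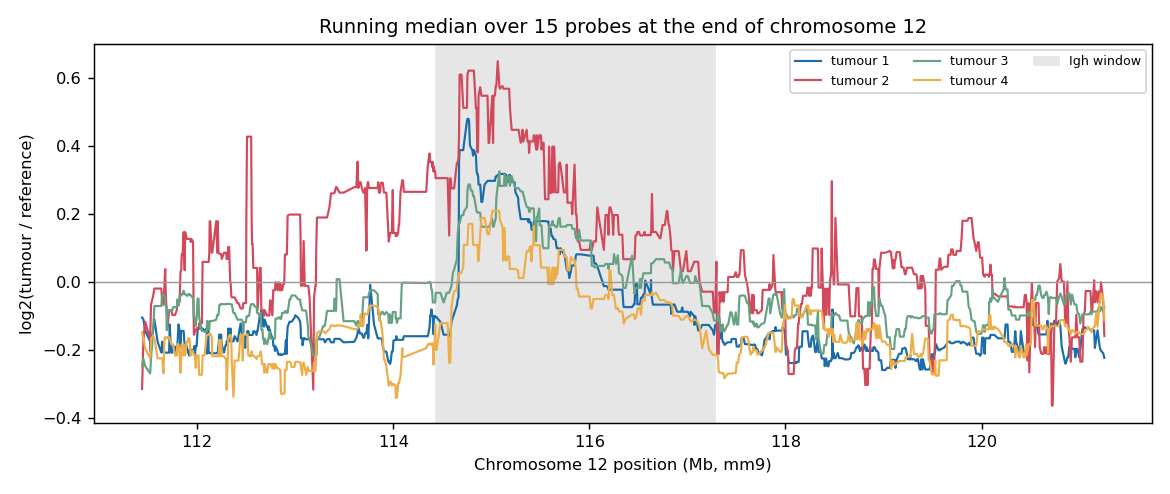
Running median over 15 probes of the log2 ratio of tumour over reference (vertical axis) along the end of chromosome 12 (horizontal axis, Mb, mm9), with a line per tumour and the Igh window shaded. All 4 lines reach the highest values of the plotted stretch within the window, which exceeded the rest of the chromosome by 0.17 to 0.29.

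The X and Y ratios of tumours 1 and 4 differed from those of tumours 2 and 3. On array 1 the reference channel stood apart and not the tumour channel. Relative to autosomal probes of the same channel, its Y level was -3.38, against -1.16 in the tumour channel. Chromosome X averaged -0.82, -0.054, -0.0061 and 0.84 in tumours 1 to 4, and chromosome Y averaged 2.22, -0.087, -0.20 and -2.35. The labels give male sex for both channels of all 4 arrays. The largest called segments of tumours 1 and 4 on these chromosomes lay in Usp9y, a Y-linked gene, at 3.77 and -3.78 for the same 6 probes (784675 to 786810). The next 2 of each also lay in Usp9y, at 2.68 (644057 to 644871) and 2.49 (632329 to 635507) in tumour 1 and at -2.82 (631964 to 635507) and -2.70 (644057 to 653926) in tumour 4. In tumour 3 the only call on these chromosomes was a loss on chromosome Y (27 to 1560020, 383 probes, -0.235), and tumour 2 had none.

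Across autosomal genes, which are not independent replicates, Pearson's r between tumours lay between 0.20 (tumours 1 and 2) and 0.49 (tumours 2 and 3). The residuals of autosomal probes, with segment means subtracted, correlated at 0.50 for tumours 2 and 3, 0.50 for tumours 2 and 4 and 0.35 for tumours 3 and 4, and at 0.12 or less for the pairs with tumour 1. The correlations between genes therefore do not measure shared copy number alone. Over all probes, r between tumours 1 and 4 was -0.61, and over the autosomal probes it was 0.18. The labels state the dyes of both arrays, so the direction of each ratio was kept. Genes called the same way numbered 845 in tumours 1 and 2, 3.96% of the autosomal genes (permutation p = 0.0074, adjusted p = 0.0444 over 6 pairs). They numbered 447 in tumours 1 and 4 and 447 in tumours 2 and 4 (adjusted permutation p = 0.0618 each), and at most 1 in the pairs with tumour 3.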

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

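The tests in this part were chosen after the results were seen. In 4 of 53 results tested, 1 tumour stood apart from the other 3 by most of the range of values, and chance gives such a value in about 1 of 20. The average of chromosome 7 was -0.072 in tumour 1, against 0.0069 to 0.020 in the others. The average of chromosome 17 was -0.074 in tumour 1, against -0.0046 to 0.0076. The average of chromosome 8 was -0.088 in tumour 2, against -0.017 to -0.0040.

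The SD between neighbouring probes was 0.36 in tumour 2, against 0.12 to 0.15 in the other tumours. Noise of single spots is argued against by the replicate spots of that array, whose SD was 0.31 of the SD between neighbouring probes. A dye bias that depends on intensity does not account for all of it, since the SD was still 0.29 with the intensity trend removed, against at most 0.14 on the other arrays. A candidate explanation that the values allow is a response of each probe that also affects the arrays of tumours 3 and 4: after segment means were subtracted, tumour 2's probes correlated with theirs at 0.50 and 0.50, and with tumour 1's at 0.12. The array also had the lowest median background-subtracted reference signal, 181.6 against 229.0 to 450.1, and whether low signal widened the spread was not tested. What sets the shared response was not tested, and no biological explanation was tested.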

How the results depend on the processing

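No paired analysis was possible because the tumours form 1 group. The planned correction for GC content over 100 kb was not run, since no genome of the files' build was used here. Between 98.9% and 99.9% of spots were well above background on each array. The share was lowest on the array of tumour 2, 98.9% in the reference channel and 99.0% in the tumour channel, against at least 99.69% on the others. The cause of each change below was not tested unless the setting itself sets it. The Trp53 and Igh averages, and those of chromosomes 15, 9 and 12, moved by less than 1 SD under every setting not named here. With normexp background correction the altered share was 8.50%, chromosome 15 averaged 0.28, genes lost in at least 2 tumours numbered 2019 (permutation p = 0.0054), genes alike over the pairs 4559 against 1741, limma called 180 higher and 211 lower, and Myc turned to -0.080. A threshold of 0.1 gave a share of 13.9%, 74 segments, 11203 genes alike over the pairs, 845 genes gained (permutation p = 0.0819) and 2052 lost (permutation p = 0.0439). A threshold of 0.3 gave 0.536%, 30 segments, 0 genes alike (permutation p = 1) and 0 gained (permutation p = 1). A penalty factor of 1.5 gave 95 segments and 5 genes lost, and a factor of 6 gave 26 segments. The running median gave 1357 segments and 315 genes lost (permutation p = 0.0005). In limma, segment means, which neighbouring genes share, gave 533 higher and 185 lower. The slide as a random block, with a correlation of -0.31, gave 169 and 192. Leaving out 1 tumour in turn gave 448 to 845 genes gained in at least 2 tumours: 448 without tumour 1 or 2, 845 without tumour 3 or 4.

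The next settings were chosen after seeing the data. Windows of 1 Mb gave 104 higher and 151 lower, and autosome means 1 higher. Tumours 2 and 3 alone gave 1 higher gene (Itln1) and 1 gene gained in both (permutation p = 0.158). With the sign of tumour 4 turned, chromosomes 15, 9 and 12 averaged 0.10, -0.026 and -0.037, the Igh excess 0.16, genes alike 884, genes lost 12, 1 list passed, and tumour 4's named segments read -1.89, -1.08 and -0.84. With that of tumour 1 turned, they averaged 0.11, -0.036 and -0.038, the Igh excess 0.11, genes alike 462 (permutation p = 0.0515), genes gained 460, genes lost 2, and its named segments read 0.66, 0.60 and 0.53. Among values of named genes 272 of 286 moved by less than 1 SD.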

Other observations

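The tests in this part were chosen after the results were seen. Between channels, the level of X and Y probes relative to the autosomal probes of the same channel set 2 channels apart. The Y level was -3.38 in the reference channel of array 1 and -3.10 in the tumour channel of array 4, and between -1.16 and -0.68 in the other 6. The X level was -0.071 and -0.068 in those channels and between -0.93 and -0.89 in the other 6.

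Turned dyes on array 1 or on array 4 are argued against by Igh only if its excess comes from a spleen reference, whose B cells lose heavy chain DNA. The excess of the locus over the rest of chromosome 12 was 0.27 ± 0.050 and 0.17 ± 0.029 (SE over blocks of probes). With that source, turned dyes would give a value below 0. The other 5 receptor loci had no like excess, with averages between -0.028 and 0.042. The labelling protocol names liver as the reference, and a difference between mice at Igh was not tested. The locus itself read 0.087 and -0.0089, so for tumour 4 the excess rests on the low ratio of the chromosome around it. That ratio was low on both sides of the locus, by a difference of 0.19 ± 0.033 from the 5 Mb before it and 0.16 ± 0.030 from the part after it (SE over blocks). A copy-number change of the tumour at the locus itself was not tested. A change of X and Y in tumour 1 against a male reference is argued against by the reference channel of array 1, whose Y level lay below the lowest of the other 3 reference channels by a difference of -2.62. For tumour 4 a somatic change cannot be told apart from DNA with 2 X chromosomes and no Y, since both give its X level, which differed from that of the reference channel of array 1 by 0.0030. Whether reference or tumour DNA was exchanged between arrays 1 and 4 stays open. Of tumour 1's 14 focal autosomal segments outside Igh, 12 had the opposite sign in tumour 4, against 4 in tumour 2 and 4 in tumour 3. However, 8 of the 14 lay on chromosome 7 and are not independent, and opposite signs had been seen before they were counted, so no p is given. Off chromosome 7 the sign was opposite in tumour 4 for 6 of 6. From the other side, 10 of 12 focal segments of tumour 4 outside chromosomes 9 and 12 had the opposite sign in tumour 1, but also 10 of 12 in tumour 3, and 6 of 12 in tumour 2. Of those off chromosome 7, the sign was opposite for 5 of 7 in tumour 1, 6 of 7 in tumour 3 and 5 of 7 in tumour 2.

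For the higher ratio of chromosome 15, probe GC content is argued against as the whole cause by comparing probes of like GC content: over 4 bins, the lowest excess of chromosome 15 over the other autosomes was 0.227 ± 0.067 (SD, n = 4). Removing a trend with probe GC content ended 3 list gains of tumour 2 and left the chromosome 15 average at 0.22 ± 0.058 (SD, n = 4). GC content over longer stretches was not tested. A trend with intensity is argued against as the whole cause by an average of 0.21 ± 0.050 (SD, n = 4) with that trend removed. A single reference with less chromosome 15 DNA is argued against by arrays 1 and 4, whose reference channels differed in Y level and whose chromosome 15 averages were 0.21 and 0.24. This comparison cannot reach a difference common to all the references, which was not tested. A gain carried by part of the tumour cells may account for the ratio, but the design has no second group and no biological explanation was tested. As a scale within the arrays, the X difference in tumours 1 and 4 read 0.82 and 0.84.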
